A study of Homo sapiens with 12 samples.

How the data were processed

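Huh7, a human hepatocellular carcinoma line, was grown for 48 h in medium with 0 or 15 µM choline. The series lists 12 samples: 4 H3K27ac or H3K4me1 ChIP-seq libraries, 4 input libraries, 3 RNA-seq samples and 1 CUT&Tag sample for KLF5. The 4 ChIP-seq libraries were analysed through their summit lists. The other 8 samples were not analysed here. Groups were taken from the labels, and each combination of mark and dose held 1 library, so no replicate spread could be measured.

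Each deposited file listed 1 summit per line with a position, a name and a score. The score was read as the −log10 of a p-value or q-value, because the authors deposited the lists in the layout of MACS2 summit files. Which of the 2 it was, and the peak-calling settings, were not given in the sources used here. The submitters' processing notes name Bowtie, Picard, deepTools and MACS2 without versions, and the genome build hg38. The lowest score was 5.01 in both H3K27ac lists, 1.31 in the H3K4me1 list at 0 µM and 1.30 in that at 15 µM, so the marks entered their lists at different thresholds, and list lengths were compared only within a mark. The score is the authors' own value and was used only to rank, describe or filter summits within a list, except that the closing section sets apart the H3K4me1 summits at 0 µM that score above the highest at 15 µM. Whether input libraries were used in calling was not given in the sources used here, and read depth is unknown. The number of summits a caller lists depends on depth and on enrichment as well as on the chromatin.

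Summits on chromosomes 1 to 22 and X were kept and written 1-based. Gene positions came from a RefSeq gene table of GRCh38.p14, the same assembly family as hg38. It gives the start and end of each gene without strand, exons or transcripts. The transcript starts planned before the data were examined were therefore replaced by gene ends, meaning either annotated end of 19974 protein-coding genes, and a summit near a gene end can lie at the transcript's start or at its other end. Exon, intron and UTR positions could not be given. The planned search for KLF-type motifs needs a genome sequence and was not run.

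A summit was shared when the other list of its mark had a summit within 500 bp. The background was the same share after shifting positions by 2 Mb. A gene end had a summit when 1 lay within 1 kb. It was counted as lost when the 15 µM list had none within 2 kb of either end of that gene, and as gained in the opposite case. Distal summits lay over 2.5 kb from every gene end. They carried H3K4me1 when an H3K4me1 summit lay within 1 kb. Distal H3K27ac summits within 12.5 kb of each other were stitched into clusters, ranked by the sum of their scores within the list, and called dense above the point where the scaled ranked curve reaches a slope of 1. No read signal entered, so dense clusters are clusters of summits and not measured super-enhancers. A cluster was lost or gained when it overlapped no dense cluster of the other list.

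For each gene, summits within 50 kb of either end were counted. The change was the 15 µM count minus the 0 µM count scaled by the ratio of the list lengths. For 18 gene lists fixed before the data were examined, the mean change was placed among 10000 random lists of the same size matched on the summed window count. This percentile describes these libraries and is not a test. Shares are given with exact Clopper-Pearson 95% intervals, which cover counting error only, and standard errors (SE) come from a jackknife over 23 chromosomes, which measures spread along the genome within the libraries. No p-value was computed between doses.

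The named genes followed a rule set before the data were examined. It took the 8 gained and the 8 lost H3K27ac gene ends with the highest scores. It took the 5 genes with the largest rise and the 5 with the largest fall in H3K27ac windows, and 8 each way for H3K4me1, skipping genes within 200 kb of one already taken. It took the nearest gene of the 5 highest-scoring gained and the 5 highest-scoring lost dense clusters, KLF5, and from each gene list the members with a gained or lost gene end and up to 2 others in list order. Other genes named were chosen after their values were seen, and the text says so. A few members of the gene lists that the rule would name are not reported here.

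The measures were checked on simulated data made from the H3K27ac list at 0 µM. All planted changes were recovered for 200 lost and 200 gained gene ends among 19974 genes (100% each). After sampling 80% of 37946 summits, 79.9% were shared. Of 200 unchanged lists of 20 genes, 4% lay outside the central 95% of random lists, and of 50 lists with about 3 added summits per gene, 100% did. The planted ends met the calling rules by construction, and the unchanged lists were themselves random draws. These checks therefore cover the computation, and not lists of neighbouring members or split summits. Alternatives covered matching distances, score limits, equal list lengths, merged summits, wider gene ends, stitching, window sizes and lists reduced to 1 member per 200 kb. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.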

Results

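The series asked how choline supply alters the enhancer marks and transcription of liver cancer cells, and what part KLF5, a zinc-finger transcription factor, has in it. H3K27ac marks active promoters and enhancers, and H3K4me1 marks enhancers, active or poised. The H3K27ac lists held 37946 summits at 0 µM choline and 29305 at 15 µM. The H3K4me1 lists held 343156 and 349202. There was 1 library for each mark and dose, so every difference below is between 2 libraries and has no replicate check.

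The first comparison was of H3K27ac between the doses. The 15 µM list was 22.8% shorter, with a ratio of list lengths of 0.772 (jackknife SE 0.0133), and it was shorter on 23 of 23 chromosomes. Around AFP, the fetal serum protein re-expressed in many liver cancers, it held 42 summits within 50 kb of the gene ends against 18 at 0 µM. Around PDGFC, a platelet-derived growth factor, it held 7 against 23. The gene ends with a summit only at 0 µM included those of ACTB and EEF2, which most cells use.

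The gene windows with the largest positive scaled differences were those of AFP, XBP1, NR1H4, VMP1 and LGR4. XBP1, a transcription factor of the unfolded protein response, had 36 summits at 15 µM and 22 at 0 µM. NR1H4, the bile acid receptor FXR, had 39 and 26. VMP1, a membrane protein of autophagy, had 42 and 30, and LGR4, an R-spondin receptor of Wnt signalling, had 47 and 39. ALB, the albumin gene beside AFP, had 44 at 15 µM and 24 at 0 µM, and its window overlaps that of AFP. The largest negative ones were those of PDGFC, ECE1, B3GAT3, GNA13 and H1-5. ECE1, the endothelin-converting enzyme, had 2 summits at 15 µM and 16 at 0 µM. B3GAT3, a glycosaminoglycan linker enzyme, had 3 and 17, as had GNA13, a G protein subunit. The histone gene H1-5 had 3 and 16. AFP (chromosome 4, 73436221 to 73456174, hg38) had its highest-scoring H3K27ac summit just outside the gene in both lists, with a score of 210 at 0 µM and 82.7 at 15 µM. The median score of its summits was 14.5 and 13.1, on scales that were not set against each other. Within 20 kb of the gene ends the order differed, with scaled differences of 15.6 for XBP1, 13.1 for VMP1, 9.50 for AFP, 8.47 for LGR4 and 7.42 for NR1H4, and of -9.58 for GNA13, -5.41 for B3GAT3, -5.18 for ECE1, -4.27 for PDGFC and -1.86 for H1-5.

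**Figure D1:**
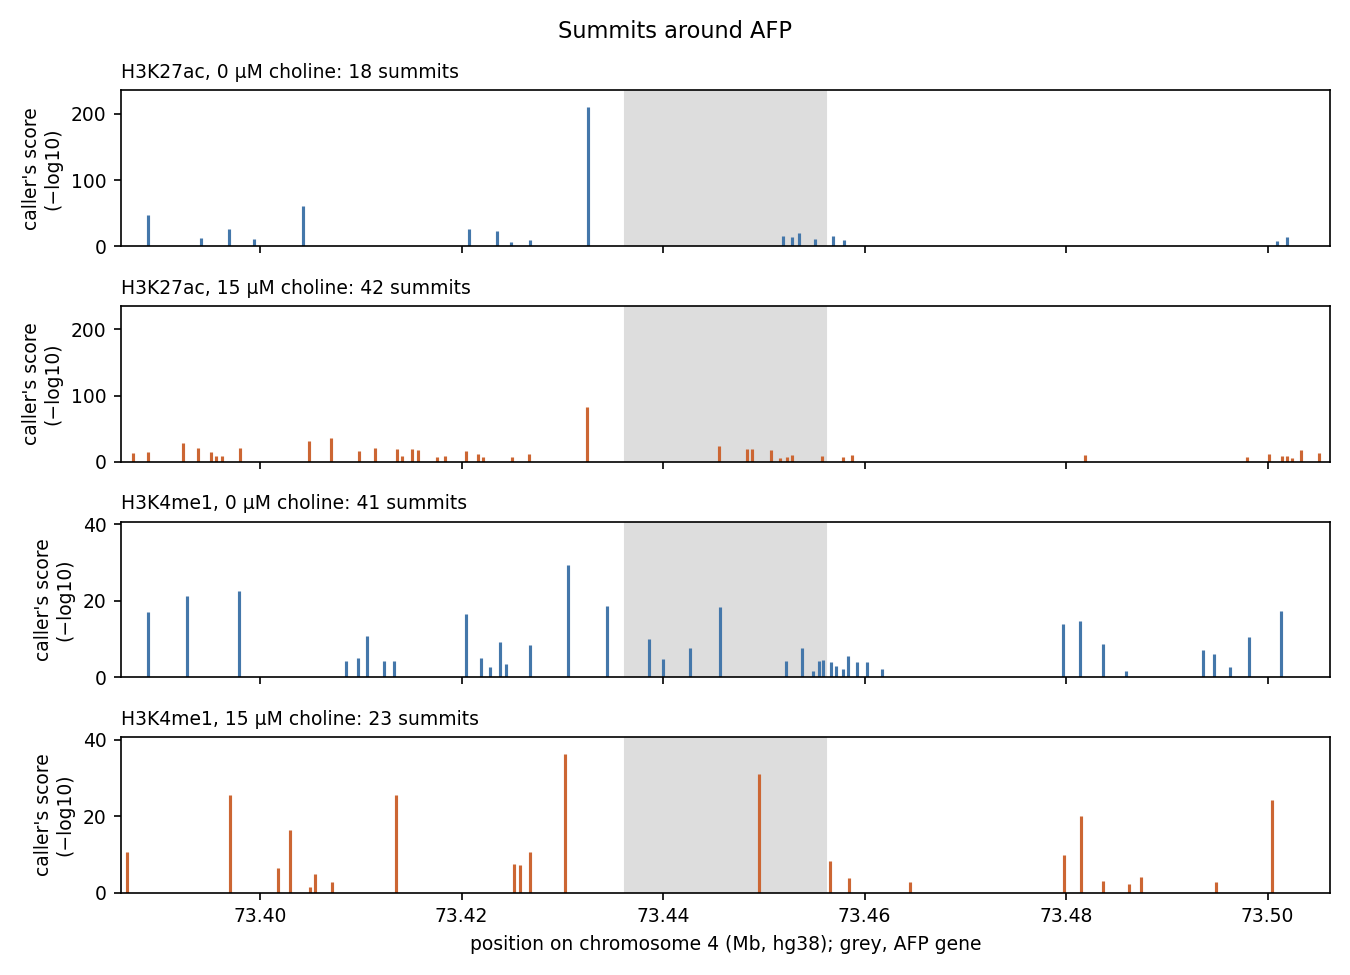
Summits of the 4 lists within 50 kb of AFP. The x axis is the position on chromosome 4 in Mb, each line is 1 summit and its height is the caller's score (−log10), and the grey block is the gene. H3K27ac had 18 summits at 0 µM and 42 at 15 µM, and H3K4me1 had 41 and 23.

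Of the 0 µM H3K27ac summits, 38.7% (95% interval 38.2 to 39.2, SE 0.504) had a 15 µM summit within 500 bp, against 1.04% after shifting. Of the 15 µM summits, 50.7% (50.1 to 51.2, SE 0.301) had a 0 µM summit, against 1.49%. Within 2000 bp, a distance chosen after seeing the data, the shares were 64.4% and 81.8%.

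Gene ends took 16.5% of H3K27ac summits at 0 µM (16.2 to 16.9) and 11.8% at 15 µM (11.5 to 12.2), a difference of -4.69 percentage points with a jackknife SE of 0.340. The share after shifting the 0 µM list was 2.67%. A total of 5648 protein-coding genes had an H3K27ac summit at an end at 0 µM and 3228 at 15 µM. Of the 5648, 2482 had none within 2 kb at 15 µM (43.9%, 42.6 to 45.3). In the opposite direction, 340 of the 3228 (10.5%, 9.49 to 11.6) had none at 0 µM. A shorter list by itself yields more lost than gained ends. With both lists cut to equal length, the counts were 2032 lost and 468 gained.

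The lost ends with the highest scores belonged to TTC9C, NELFA and its neighbour LOC124900839, which share 1 summit, and to DUSP1, TUBA1B, ITFG2, CTR9 and ALG2. NELFA is a subunit of the complex that pauses RNA polymerase II, and CTR9 a subunit of the elongation factor PAF. DUSP1 is a phosphatase that switches off MAP kinases, TUBA1B an alpha-tubulin and ALG2 a mannosyltransferase of N-glycosylation. The TUBA1B window held 3 H3K27ac summits at 0 µM and 0 at 15 µM, and that of ITFG2 held 5 and 0. The gained ends with the highest scores were those of ITIH2, FLRT3, ID1, NQO1, SRRM1, PDE8A, CYP2C18 and UBE2H. ITIH2 encodes a plasma protease inhibitor chain made in the liver, ID1 an inhibitor of basic helix-loop-helix factors and NQO1 a quinone reductase of the antioxidant response. The ID1 window held 10 summits at 0 µM and 16 at 15 µM, whereas that of NQO1 held 14 and 15. Of the 8 windows, 4 held more summits at 15 µM and 4 fewer, among them FLRT3 with 6 and 5 and CYP2C18 with 5 and 3. Requiring absence within 10 kb, an alternative chosen after seeing the data, left 1936 lost and 184 gained ends. Among the 8 named gained ends, only that of SRRM1 met this requirement, and among the 8 lost ones those of TTC9C and DUSP1 did not.

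**Figure D2:**
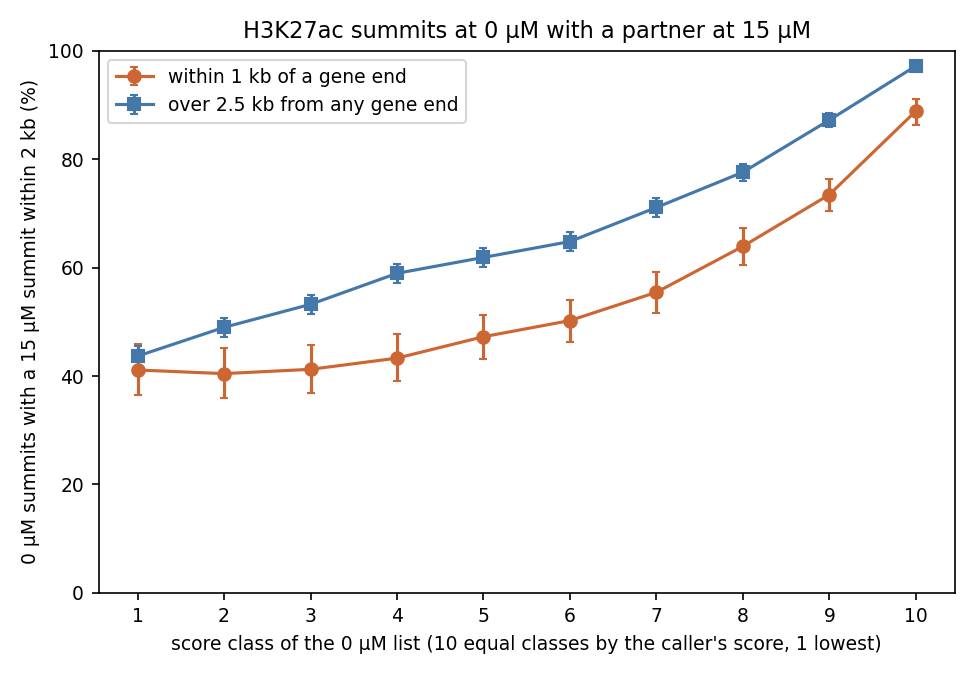
Share of 0 µM H3K27ac summits with a 15 µM summit within 2 kb, in percent (y axis), by score class of the 0 µM list, 10 classes of equal size ranked on the caller's score (x axis). Circles are summits within 1 kb of a gene end, squares are summits over 2.5 kb from every gene end, and bars are exact 95% intervals. In the highest class the shares were 88.9% at gene ends and 97.2% away from them.

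Gene lists were compared next. The hepatocyte list, which holds plasma proteins, apolipoproteins and metabolic enzymes, had 252 H3K27ac window summits at 0 µM and 274 at 15 µM over 28 genes. ALB supplied most of that difference, as the other 27 genes had 228 and 230 in windows that partly overlap, and with 1 member per 200 kb and without ALB the counts were 169 and 162. Its mean scaled change was 2.84 summits per gene, at the 99.9th percentile of matched random lists, and 16 members had a positive and 8 a negative scaled change. FGA, FGB and FGG, the fibrinogen chains, had 27 summits each at 15 µM, against 22, 22 and 21 at 0 µM, in overlapping windows. APOA1, the main protein of high-density lipoprotein, had 12 against 9, and RBP4, the plasma retinol carrier, 7 against 4. TTR, the thyroid hormone carrier transthyretin, had 2 against 3, SERPINA1, the alpha-1 antitrypsin gene, 13 against 19, and APOB 6 against 12. FGA, FGB, FGG, APOA1, RBP4, SERPINA1 and APOB were chosen after their values were seen. None of the 15 hepatocyte genes with a summit at an end at 0 µM had lost it, and 18 had one at 15 µM. With 1 member per 200 kb, chosen after seeing the data, the list of 24 genes stood at the 99.8th percentile with a mean change of 2.37. ALB had the largest change of the list. Without ALB, also chosen after seeing the data, the mean change was 2.0 at the 98.7th percentile over 27 genes, but 1.37 at the 93.2nd percentile, inside the range, over the 23 genes left with 1 member per 200 kb.

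The liver transcription factors had 294 H3K27ac window summits at 0 µM and 297 at 15 µM, a mean change of 2.91 at the 96.2nd percentile, inside the central 95% of random lists. Of their 16 gene ends with a summit at 0 µM, 3 were lost, at HNF4G, ATF5 and TBX3. The betaine and methionine cycle, which passes methyl groups from choline to S-adenosylmethionine, had 59 and 56 window summits and a mean change of 0.55 at the 99.5th percentile. Of its 10 gene ends with a summit at 0 µM, 4 were lost (40%, 12.2 to 73.8), against 43.9% over all genes. They were those of CHDH, the enzyme that oxidises choline, ALDH7A1, SHMT2 and MTHFD2. BHMT, which remethylates homocysteine with betaine, had 3 summits at 0 µM and 4 at 15 µM. BHMT, BHMT2 and DMGDH, the last chosen after its values were seen, are neighbours, and with 1 member per 200 kb this list stood at the 93.1st percentile, inside the range.

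Choline uptake and phosphatidylcholine synthesis had 120 window summits at 0 µM and 90 at 15 µM, at the 36.4th percentile. SLC44A1, a choline transporter, had 14 and 10, and SLC44A2 had 4 and 2. The windows do not reach the middle of SLC44A1, where a gained dense cluster lay. Its span held 7 summits at 15 µM and 3 at 0 µM. This cluster was chosen after its values were seen. Of the 10 gene ends of the choline list with a summit at 0 µM, 3 were lost (30%, 6.67 to 65.2), against 43.9% over all genes. They were those of PEMT, which methylates phosphatidylethanolamine to phosphatidylcholine, GPCPD1 and LPCAT3. The cell cycle list had 119 and 68 summits at the 6.92nd percentile. Of its 9 gene ends with a summit at 0 µM, 4 were lost, at MYC, E2F3, MKI67 and MCM3, and MYCN gained one. MYC, a growth-promoting transcription factor, had 3 summits at 0 µM and 0 at 15 µM.

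Of the YAP and TEAD targets, 7 of 11 gene ends with a summit at 0 µM were lost (63.6%, 30.8 to 89.1), at CCN1, CCN2, TEAD4, AXL, F3, ARHGEF17 and GADD45A, and LATS2, a Hippo pathway kinase, gained one. Of the inflammation list, 5 of 8 were lost, at RELA, a subunit of NF-κB, RELB, CXCL2, ICAM1 and STAT3, and of the chromatin enzymes 7 of 13, among them DNMT1 and EZH2. Of the amino acid and ER stress list, 6 of 14 were lost, at ATF4, its central activator, ATF6, TRIB3, CHAC1, SESN2 and PHGDH. Of the sterol and fatty acid list, 3 of 17 were lost, at SREBF1, INSIG1 and ACLY, and IDI1 gained one. ZEB1, MMP14, ITGA6 and TGFB1 of the mesenchymal list, SOX9 and ANXA3 of the oncofetal list, GPI and VEGFA of the glycolysis list, KLF9 of the KLF and SP factors and SNAP25 of the neuron and muscle markers had lost ends, and IGF2BP1 of the oncofetal list a gained one. Of the ubiquitous genes, 8 of 15 were lost (53.3%, 26.6 to 78.7), at ACTB, TUBA1B, RPL13A, RPS18, EEF2, HSP90AB1, PSMB2 and VCP, and SDHA gained one. Against the 43.9% over all genes, the interval lay below for the sterol and fatty acid list (3.80 to 43.4) and for the hepatocyte list (0 to 21.8), and it included that value for every other list. The 43.9% was not matched on window counts. Hepatocyte genes averaged 9 H3K27ac window summits at 0 µM, against a median of 2 over all genes. A loss requires no 15 µM summit within 2 kb, so it depends on how densely summits lie. The intervals also treat neighbours such as FGA, FGB and FGG as independent.

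**Figure D3:**
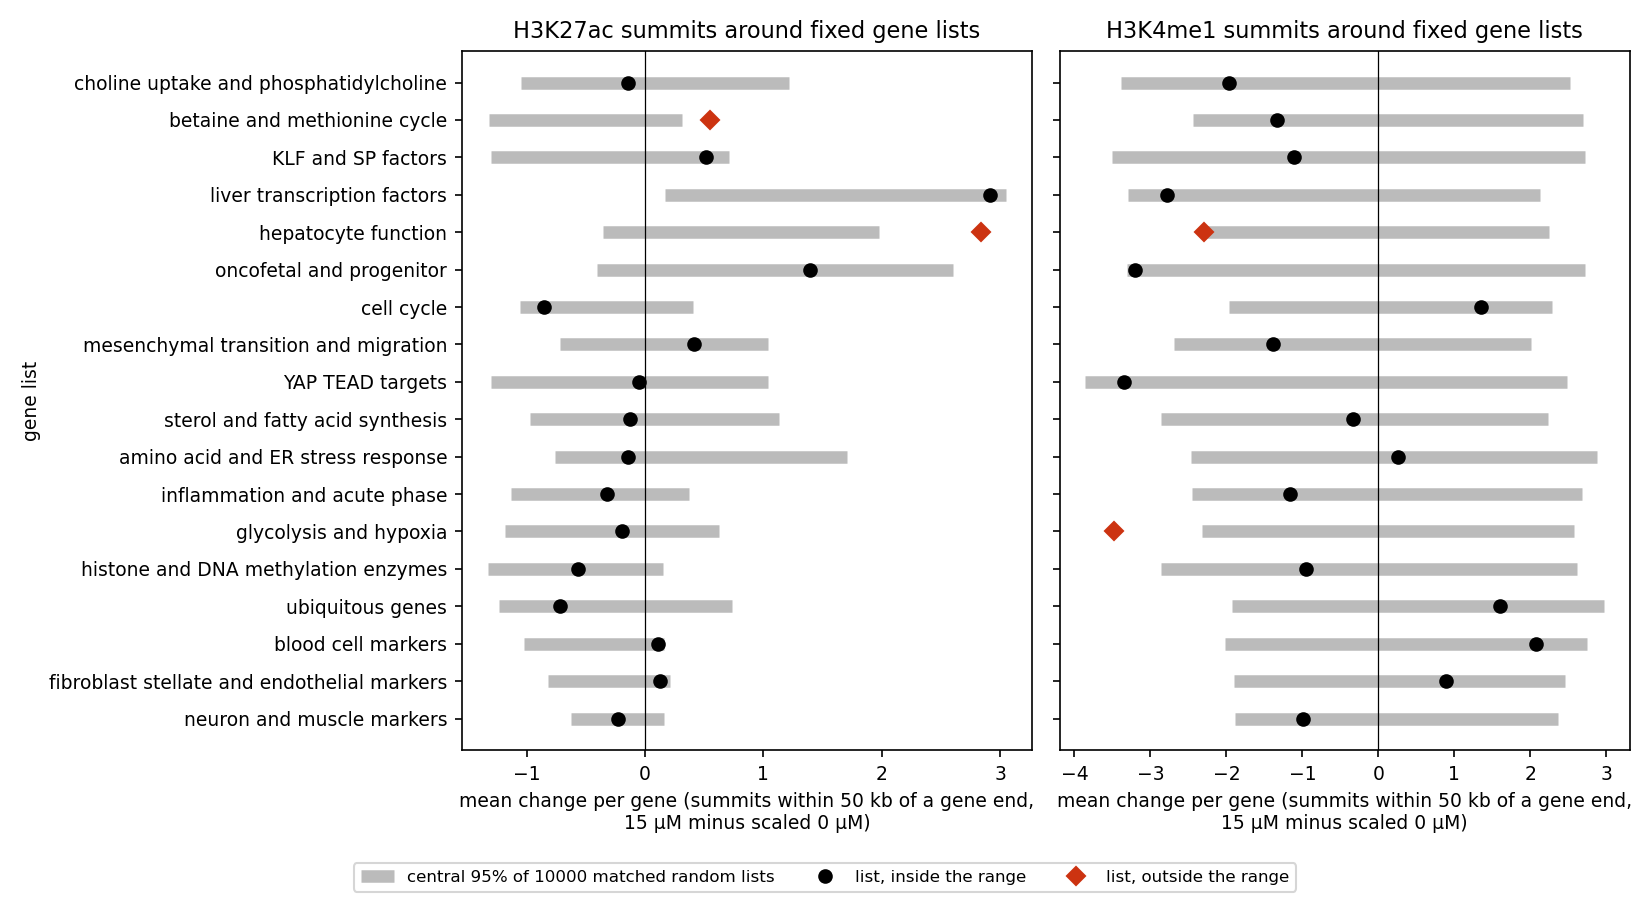
Mean change per gene in summits within 50 kb of a gene end (x axis, 15 µM minus scaled 0 µM) for the 18 fixed gene lists (y axis), H3K27ac on the left and H3K4me1 on the right. Grey bars span the central 95% of 10000 matched random lists, circles are lists inside that range and diamonds lists outside it, which were 4 of 36.

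The remaining lists lay inside the central 95% for H3K27ac. Their percentiles were 93.6 for KLF and SP factors, 69.5 for oncofetal genes, 74.8 for mesenchymal and migration genes, 57.1 for YAP and TEAD targets, 36.6 for sterol and fatty acid synthesis, 18.4 for amino acid and ER stress, 55.6 for inflammation, 57.2 for glycolysis and hypoxia, 51.0 for chromatin enzymes and 18.1 for ubiquitous genes. The markers of other cells had few H3K27ac summits. Blood cell markers had 31 at 0 µM and 26 at 15 µM (96.8, but 79.98 with 1 member per 200 kb, where the mean change went from 0.114 to -0.136), fibroblast, stellate and endothelial markers 23 and 20 (95.5), and neuron and muscle markers 17 and 9 (48.6). CD3E, a T cell receptor subunit, had 0 and 2 summits and a gained end, in a window that overlaps those of CD3D and CD3G. Members taken in list order had these H3K27ac counts at 0 and 15 µM. GPC3, a fetal proteoglycan of liver cancers, had 40 and 25, KLF2 had 0 and 1, KLF3 had 9 and 9, and CCND1, a cyclin of the G1 phase, had 10 and 11. SNAI1, a repressor of E-cadherin, had 2 and 5, ANKRD1 had 6 and 3, AMOTL1 had 7 and 9, and SREBF2, the activator of cholesterol synthesis, had 13 and 18. ATF3 had 1 and 0, DDIT3 had 7 and 2, NFKB1 had 11 and 10, NFKBIA had 2 and 2, DNMT3A had 2 and 0, DNMT3B had 3 and 1, and TUBB had 10 and 7. Those without a summit at either dose were CCND2, SNAI2, SLC2A1, ACTG1, NEUROD1 and NEUROG2. SLC2A3 had 2 and 0, PTPRC had 1 and 0, CD3D had 0 and 2, COL1A1 had 2 and 1, and COL1A2 had 4 and 5.

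Chance alone would put 1.8 of the 36 percentiles of both marks outside the range, where 4 lay. With 1 member per 200 kb, 2 lay outside.

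The KLF5 locus was compared because the study centres on this factor. KLF5 (chromosome 13, 73054976 to 73077538, hg38) had 6 H3K27ac summits within 50 kb at 0 µM and 12 at 15 µM, a scaled change of 7.37. This was at the 99.3rd percentile of all protein-coding genes and the 98.2nd of 767 genes with a similar total. In both lists the highest-scoring KLF5 summit lay outside the gene, at 73040927 at 0 µM and at 73040968 at 15 µM. At 15 µM, 3 further summits lay beside it, at 73038571, 73039494 and 73039931. H3K4me1 had 30 KLF5 summits at 0 µM and 39 at 15 µM. The KLF5 summits lay in 3 bins of 5 kb at 0 µM and in 6 at 15 µM. Their highest score was 39.9 in the 0 µM list and 21.5 in the 15 µM list, and their median 18.9 and 8.71, on scales that were not set against each other. Within 100 kb, the H3K27ac counts around KLF5 were 12 and 15. KLF6, a relative of KLF5 chosen after its values were seen, had 7 H3K27ac summits at 0 µM and 12 at 15 µM.

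**Figure D4:**
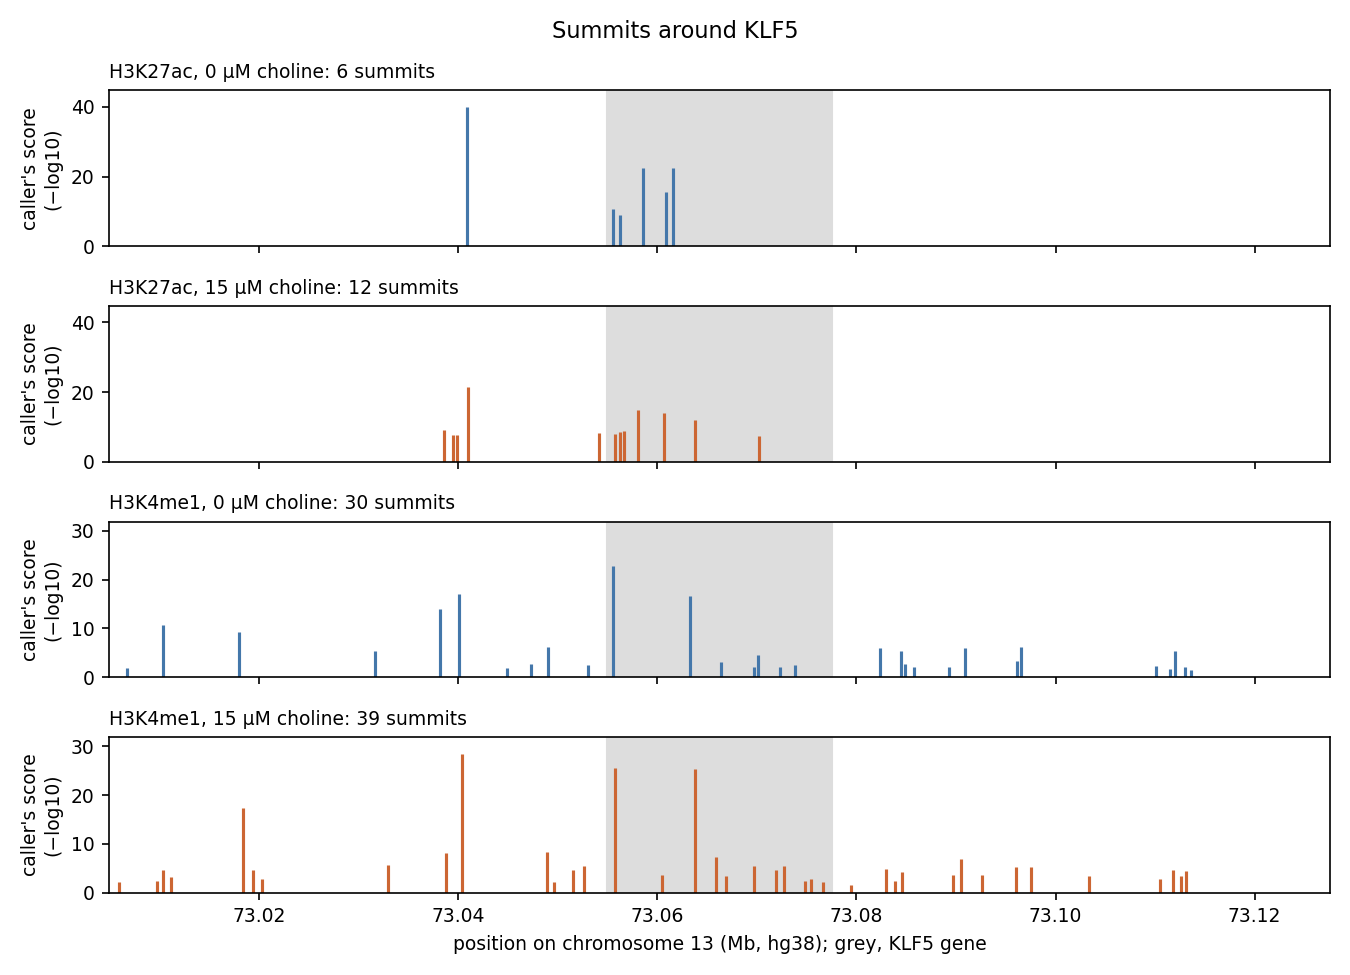
Summits of the 4 lists within 50 kb of KLF5. The x axis is the position on chromosome 13 in Mb, each line is 1 summit and its height is the caller's score (−log10), and the grey block is the gene. H3K27ac had 6 summits at 0 µM and 12 at 15 µM, and H3K4me1 had 30 and 39.

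Dense clusters of distal H3K27ac summits stand in for large enhancers, which the series also asked about. Ranking by summed score let some clusters of 1 high-scoring summit qualify as dense, and such clusters were among those called lost. The 4 highest-ranked clusters were the same at both doses and lay at FNDC3B, ADGRG6, COBLL1 and DIP2B. At 15 µM, clusters at TLE1, ALB, LGR4 and NR1H4 ranked next, and at 0 µM those at NRP1, RERE, SPTBN1 and RPS6KA3. All these genes were chosen after the ranks were seen, and the ranks come from lists of different length. Of 683 dense clusters at 0 µM, 243 overlapped none at 15 µM (35.6%, 32.0 to 39.3), and of 537 at 15 µM, 98 overlapped none at 0 µM (18.2%, 15.1 to 21.8). The highest-scoring lost clusters lay nearest to LOC124906109 (inside INPP1), IRF2BP2, ELOVL2, SLC38A2 and DIXDC1. In this order, they held 10, 11, 16, 11 and 14 distal summits at 0 µM. The 15 µM list had 12, 11, 14, 8 and 8 summits in the same spans, counted with those near gene ends. These stretches thus still held summits at 15 µM, although they overlapped no dense cluster. ELOVL2 elongates polyunsaturated fatty acids, and SLC38A2 is a neutral amino acid transporter. The highest-scoring gained ones lay nearest to ZNF367, LPP, WWOX, ST3GAL6 and FGA. The FGA cluster held 10 distal summits at 15 µM. The 0 µM list had 14 summits in the same span, but that count includes summits near gene ends, so the counts are not alike. Lost and gained clusters each held a median of 5 summits of the other list, counted with those near gene ends, which do not enter clusters. The span held no summit of the other list at 6 lost and 0 gained clusters, so most stretches were not empty at the other dose. Both counts, and the excess of lost over gained clusters, depended on the processing. With 5 kb stitching, 339 were lost and 233 gained, with summits near gene ends kept 248 and 172, at equal list lengths 171 and 145, and among the 500 highest clusters of each list 146 and 145.

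The second comparison was of H3K4me1 between the doses. The 15 µM list had 1.02 times as many summits (SE 0.00852), more on 16 chromosomes and fewer on 7. Around AFP it held 23 summits against 41 at 0 µM, and around ALB 20 against 37. The median score of the AFP summits was 7.55 at 15 µM and 5.54 at 0 µM, on scales that were not set against each other. For ALB it was 7.95 and 4.75. Whether fewer summits there mean less H3K4me1 or summits joined into fewer was not tested. Genes of glycolysis and the hypoxia response held 530 summits at 15 µM and 596 at 0 µM. Gene ends took 4.10% of H3K4me1 summits at 0 µM and 4.07% at 15 µM, a difference of -0.030 points (SE 0.035).

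The H3K4me1 windows with the largest positive scaled differences were those of MBNL1, NOTCH2, PSPC1, SPATA13, ISL2, ERC1, POLK and CD3E. MBNL1, a splicing regulator, had 60 summits at 15 µM and 33 at 0 µM, and NOTCH2, a Notch receptor, had 74 and 49. POLK, a translesion DNA polymerase, had 57 and 35. The largest negative ones were those of MAN1A1, RAI14, TLE1, LIN7A, AFF3, SMAD3, SPTLC1 and MED19. MAN1A1, a mannosidase of N-glycan trimming, had 53 and 84. TLE1, a transcriptional corepressor, had 53 and 79, while its H3K27ac summits numbered 50 at 15 µM and 45 at 0 µM. SMAD3, a TGF-β signal transducer, had 46 and 68, and SPTLC1, a subunit of the first enzyme of sphingolipid synthesis, had 19 and 41.

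Glycolysis and hypoxia genes had a mean H3K4me1 change of -3.48 summits per gene, at the 0.170th percentile of random lists, with 6 members positive and 16 negative. These signs are of scaled changes, and some of the negative members had equal unscaled counts at both doses. PKM, the pyruvate kinase of proliferating cells, had 28 summits at 15 µM and 46 at 0 µM, and VEGFA, the angiogenic growth factor, 27 and 40. PKM was chosen after its values were seen. Hepatocyte genes had a mean change of -2.29 at the 2.5th percentile, at the edge of the central 95%. With 1 member per 200 kb they stood at the 8.23rd percentile, inside it, as they did at the 6.39th without ALB. The liver transcription factors stood at the 5.83rd percentile, oncofetal genes at the 3.09th, YAP and TEAD targets at the 5.22nd, and choline uptake at the 15.0th. Blood cell markers stood at the 91.8th, with CD3E at 39 summits against 18. CD3D, CD3E and CD3G are neighbours, and with 1 member per 200 kb the list stood at the 42.0th, with a mean change of 0.055. The other lists lay between the 12.3rd and the 87.0th percentile.

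Of the 0 µM H3K4me1 summits, 44.5% (44.3 to 44.6) had a 15 µM summit within 500 bp, against 12.4% after shifting. Of the 15 µM summits, 43.5% (43.3 to 43.7) had a 0 µM summit, against 12.1%. H3K4me1 was at the ends of 10314 genes at 0 µM and 10563 at 15 µM, with 920 lost and 1150 gained.

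The third comparison joined the marks, since H3K27ac with H3K4me1 away from gene ends is the usual sign of an active enhancer. Of distal H3K27ac summits, 67.1% (66.5 to 67.6) carried H3K4me1 of the same dose within 1 kb at 0 µM and 58.8% (58.1 to 59.4) at 15 µM, against 21.4% and 22.3% after shifting. The difference was -8.32 points (SE 0.502). It turned to 2.80 points (SE 0.469) when H3K4me1 summits were limited to scores of 10 or more, with 37.0% at 0 µM and 39.8% at 15 µM. That limit left 32692 H3K4me1 summits at 0 µM and 39414 at 15 µM. A longer list by itself raises the share, and no shifted background is given for this limit. The distal H3K27ac summits of 0 µM carried 15 µM H3K4me1 at 60.9%, and those of 15 µM carried 0 µM H3K4me1 at 65.3%, so over all scores the share followed the H3K4me1 list more than the H3K27ac list. With H3K4me1 scores of 10 or more, a crossing chosen after seeing the data, these shares were 38.7% and 38.6%, and it followed neither list more than the other. Distal H3K27ac summits without a 15 µM partner within 2 kb carried H3K4me1 at 70.7% in the 0 µM list and at 66.6% in the 15 µM list. Those found at 15 µM without a 0 µM partner carried it at 66.9% in the 0 µM list and at 62.5% in the 15 µM list.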

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

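The tests of sensitivity, splitting and amplified fragments were fixed before their results were seen. The tests of ubiquitous genes, H3K4me1 domains and choline dose were chosen after, as was the repeat at 500 bp.

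The marks differed in the direction of their list lengths: the ratio of 15 to 0 µM was 0.772 for H3K27ac and 1.02 for H3K4me1. Around AFP the ratio of summit counts was 2.33 for H3K27ac and 0.561 for H3K4me1. Neither difference was tested, because each mark had 1 library per dose. Summits on unplaced contigs, outside the chromosomes compared, numbered 35 and 26 in the H3K27ac lists at 0 and 15 µM and 399 and 398 in the H3K4me1 lists, above the limit of 3 that a count of 0 allows.

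H3K27ac gene ends were listed less often at 15 µM. The prediction was that a less sensitive 15 µM list loses gene-end and distal summits of the same score alike. Standardised to 10 score classes, however, the share of gene-end summits with a 15 µM summit within 2 kb was -12.4 points relative to distal ones (SE 1.0). Within 500 bp it was -7.69 points (SE 0.737), which missed the limit of 10 points set for the first value. At equal score, gene-end summits thus had a partner less often at both distances. Any nearby summit counts as a partner, and the score classes do not equalise how closely summits are spaced. A uniform loss of sensitivity is therefore not excluded. Ubiquitous genes were among those that lost ends, 8 of 15 (53.3%, 26.6 to 78.7), and since this interval includes the 43.9% of all genes, a loss that falls more on lowly used genes stays open. An effect of choline dose may equally lie behind it, and 1 library per dose cannot tell it apart from a difference in enrichment or base composition between the libraries.

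More H3K27ac summits at 15 µM were listed around AFP, XBP1, NR1H4, VMP1 and LGR4. Splitting of the same acetylated stretches into more summits stays open. The ratio of occupied 5 kb bins had a median of 1.18, between the limits of 1 and 1.2 set for it. It ranged from 0.947 at VMP1 to 1.70 at AFP. Occupied bins fell from 19 to 18 at VMP1 and rose at the other genes. Summits per occupied bin were higher at 15 µM at each of these genes, so closer spacing was part of each rise. They went from 1.8 to 2.47 at AFP, from 2 to 2.77 at XBP1 and from 1.53 to 1.95 at NR1H4. At VMP1 they went from 1.58 to 2.33, and at LGR4 from 1.86 to 1.96. Over the whole H3K27ac lists they were 1.53 at 0 µM and 1.59 at 15 µM. An effect of choline dose is a possible explanation that 1 library per dose leaves untested.

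The H3K4me1 list at 0 µM held 46 summits with scores from 207 to 15025, above the highest score of 158 at 15 µM, the highest in FAT1, ZBTB10, AVPR1B, CREBZF and PDIA4, chosen after their values were seen. Peaks of broad H3K4me1 domains are unlikely, since the highest other summit within 5 kb exceeded the list's 90th percentile at 9 of the 46 sites. Of the 46, 45 lay in protein-coding genes (97.8%, 88.5 to 99.9), against 54.8% of 5000 other summits, and 5 had a 15 µM summit within 500 bp. Amplified fragments of transcribed genes could give such isolated summits, but their median distance to a gene end was 0.165 of the gene's length against 0.245 for the others, which does not reach the halving set for that explanation, so it stays open. An effect of choline dose on these summits was not tested.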

How the results depend on the processing

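The difference between doses in distal H3K27ac summits with H3K4me1 reversed, from -8.32 points to 2.80 with scores of 10 or more, and was -6.74 within 500 bp and -6.17 within 2 kb. The mean change of gene lists changed sign in 6 of 36 cases at 20 kb, 4 at 100 kb, 1 at equal lengths and 1 with 1 member per 200 kb, in lists inside the random range. No paired analysis was possible because each group held 1 library, and no library could be left out. Alternatives not run were 1 start per gene and the KLF motif settings, which need transcripts or a genome. The 2000 bp matching, absence within 10 kb, the KLF5 window of 20 kb, the lists without the extreme summits, 1 member per 200 kb, leaving out list members and crossing the doses at H3K4me1 scores of 10 or more were chosen after seeing the data. Except where equal lengths or a narrower distance changes a value by construction, the cause was not tested. Unknown depth limits all counts.

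The share of 0 µM H3K27ac summits found at 15 µM, and the reverse, was 22.3% and 28.9% at 200 bp, 52.1% and 68.2% at 1000 bp, 64.4% and 81.8% at 2000 bp, 35.6% and 49.7% for scores of 10 or more, 44.0% and 45.3% at equal lengths, and 34.7% and 46.0% with summits merged. For H3K4me1 these were 22.2% and 21.9%, 62.3% and 60.6%, 76.6% and 74.9%, 41.5% and 34.4%, 44.2% and 43.9%, and 38.2% and 37.2%. Gene ends within 2 kb took 22.7% of H3K27ac summits at 0 µM and 17.8% at 15 µM. At 0 µM they took 19.4% for scores of 10 or more and 17.9% at equal lengths. Gained gene ends numbered 184 with absence within 10 kb. Distal H3K27ac summits with H3K4me1 were 41.9% at 0 µM and 35.2% at 15 µM within 500 bp, 87.7% and 81.6% within 2 kb, and 37.0% and 39.8% with scores of 10 or more. Gained dense clusters numbered 233 with 5 kb stitching and 172 with summits near gene ends kept, and 146 were lost among the 500 highest. Lists outside the random range numbered 1 for each mark with 1 member per 200 kb and 5 for H3K4me1 with 20 kb windows. KLF5 had 12 H3K27ac summits at 0 µM within 100 kb, and 55 and 63 H3K4me1 summits. Of the 36 list percentiles, 22 moved by over 10 points at 20 kb, 21 at 100 kb and 7 at equal lengths. Of 26 named windows, 23 moved at 20 kb and 3 at 100 kb, with no change of sign. Leaving out each of 19 betaine and 22 glycolysis members kept these lists outside the range, as it did for 28 hepatocyte members in H3K27ac but for 15 of 28 in H3K4me1. The gene-end calls of 6 of 16 named genes ended with ends within 2 kb and those of 9 with absence within 10 kb.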

Other observations

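The relation over chromosomes was looked for after the data were seen. Of the 10 genes named for H3K27ac windows, 8 had scaled changes of opposite sign in the marks and 2 of the same sign, and of the 16 named for H3K4me1, 10 and 4. These signs depend on the scaling. By unscaled counts, MAN1A1, LIN7A and SMAD3, counted as opposite, had fewer summits of both marks at 15 µM, and MED19 had equal H3K27ac counts. MBNL1 and ISL2, counted as the same, had fewer H3K27ac and more H3K4me1 summits at 15 µM. NR1H4 had 71 H3K4me1 summits at 0 µM and 60 at 15 µM, VMP1 72 and 64, LGR4 57 and 47 and XBP1 35 and 31, each beside more H3K27ac summits at 15 µM. B3GAT3 went the other way, with 27 and 39 H3K4me1 summits beside fewer of H3K27ac. PDGFC, with 60 and 47 H3K4me1 summits, and ECE1, with 36 and 31, had fewer of both marks at 15 µM, and KLF5, with 30 and 39, had more of both. PROX1, a regulator of liver development chosen after its values were seen, had 30 and 39 H3K27ac summits and 56 and 43 H3K4me1 summits. Across 19974 genes, which are not independent replicates, the scaled changes of the marks had a Spearman correlation of -0.066.

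Per chromosome, the ratios of list lengths of the marks were related inversely over 23 chromosomes, with Pearson's r = -0.645 (permutation test, two-sided, p = 0.00047) and Spearman's rho = -0.502 (p = 0.0158, permutation test), 1 relation computed. Chromosomes are parts of the same libraries, so these p-values say nothing about the doses. Without chromosomes 12 and X, the farthest from the median in H3K27ac, r was -0.536. This check kept chromosome 20, with an H3K27ac ratio of 0.872 and the lowest H3K4me1 ratio, 0.874. The correlation without chromosome 20 was not computed.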
